A study of Canis lupus familiaris with 12 samples.

How the data were processed

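Messenger RNA levels were measured in Mi/CMM1, a cell line from a dog oral melanoma, with Agilent one-colour (Cy3) dog arrays. There were 12 arrays, 3 for each of 4 groups: untreated cells and cells given piroxicam, carprofen or robenacoxib, 3 nonsteroidal anti-inflammatory drugs that inhibit cyclooxygenases. Per the labels' protocols, each drug was given at its half-maximal inhibitory concentration, total RNA was purified with the RNeasy Mini kit, RNA integrity numbers were above 9.0, and cRNA was labelled with the Quick Amp kit together with the One-Color RNA Spike-In kit. The labels conflict on dose and time. The sample labels and the series design give piroxicam at 116 µM, carprofen at 779 µM and 6 h of exposure. The treatment protocol gives piroxicam at 779 µM, carprofen at 116 µM and 24 h. Robenacoxib is at 156 µM in both. Which version is right was not settled here, so the doses of the drugs differ in either version and no dose was matched. The control label reads no treatment and names no vehicle.

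Per the file headers, the arrays were read with Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09, and the deposited scanner files hold spot intensity, background-subtracted within each array and not normalized between arrays. The authors' deposited value table was made with limma 3.24.15, per the submitters' processing notes, and holds values on a log2 scale as judged from the numbers. Its column medians were all 7.67. Normexp background correction without an offset on the median signals, followed by quantile normalization, gave values that differed from this table by a median of 0.008, while the authors' own background correction and normalization are not given in the sources used here. The table served as an alternative.

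Intensities were analysed with R 4.3.3, limma 3.58.1 and version 1.17.8 of data.table. The processed signal was put on the log2 scale and each array's 75th percentile was subtracted. Control spots and spots with an outlier flag were left out, and spots of a probe were averaged. Of 43603 distinct probes, 31996 were well above background on all 3 arrays of at least 1 group and were tested; 28346 were well above background on all 12 arrays. No spot was saturated (0 over all arrays). A log2 fold change of a dim probe rests on signal near background and may be too large or too small. Of 135 probes at least 2-fold lower with piroxicam than in control, 18 were well above background on all 12 arrays. For a gene not well above background on any array of a group, a fold is given as a lower bound: the brighter group's mean against, per array, the higher of the dim probe's signal and the lowest signal among probes well above background. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.053.

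One linear model was fitted with limma (lmFit and eBayes, 8 residual degrees of freedom) to all 12 arrays, so that the groups shared 1 estimate of spread per probe. Each drug was compared with control and with each other drug in two-sided tests, with Benjamini-Hochberg adjustment over the 31996 probes within each comparison and a threshold of 0.05. An overall F-test covered the 3 drug-minus-control coefficients. The series design calls the replicates biological; nothing more is said of how the cultures were separated.

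The arrays lay on 3 slides. Slide 1 held the 3 controls and carprofen 1; slide 2 held carprofen 2 and 3 and piroxicam 1 and 2; slide 3 held piroxicam 3 and the 3 robenacoxib arrays. Each slide was scanned as a unit, so slide and scan cannot be told apart. Control shared no slide with piroxicam or robenacoxib, and carprofen shared none with robenacoxib. Every comparison was therefore also fitted with slide as a block, and within a slide where one held both groups. The slides link the groups in a chain, so the block estimate of carprofen against control is carprofen 1 against the 3 controls, that of carprofen against piroxicam comes from slide 2 and that of robenacoxib against piroxicam is 3 arrays against piroxicam 3. The remaining block estimates are sums of these, and the block fit differs from the fits within 1 slide only in the spread, which it takes from all arrays.

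Names came from a RefSeq gene table of the dog assembly UU_Cfam_GSD_1.0, used for names only, through the accession of each probe. It named 1313 probes (3.01%) with 832 symbols, and 42290 probes stayed unnamed, among them all 17073 probes with a predicted-transcript accession. The named genes are thus a small part of the array: 614 had a tested probe. A gene was read on its tested probe with the highest mean over the 12 arrays, and disagreement between probes is stated.

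The design, the tests, 27 gene lists and the rule for naming genes were set before the data were examined. The rule took, for each drug, up to 8 genes higher and 8 lower by at least 2-fold with groups that did not overlap; up to 3 changed members of each list; 12 genes fixed by name, of which 4 (PTGS1, PTGS2, PTGES and MITF) had a tested probe; the 6 genes higher and 6 lower with all 3 drugs; and up to 5 each way between drugs. Few genes reached 2-fold, so the same ranking without the fold minimum, kept to genes well above background on all 12 arrays, was added after the values were seen. Some genes are left out for length, for the most part genes whose calls hung on single arrays or ended under several alternatives. The rule did not set this choice by outcome, so the genes described may look firmer than the full set. Left out against control are the 2-fold genes of piroxicam, VNN1 (1.37), SAG (-1.47), DLA-DQB1 (-1.41) and AANAT (-1.12), and TBXT with robenacoxib (2.31). Also left out are P2RX7, which ranked first among the genes higher with all 3 drugs, and IL12RB2. P2RX7 changed by 0.57, 0.44 and 0.45 with piroxicam, carprofen and robenacoxib, but by 0.12, 0.09 and 0.12 with slide as a block. IL12RB2 changed by 0.59, 0.35 and 0.51 in the same order. Between drugs, the 2-fold genes VNN1 (-1.29, robenacoxib against piroxicam) and AANAT (1.15, carprofen against piroxicam) are left out. Lists with at least 3 tested members, 12 of the 27, were tested with camera in limma on 1 probe per gene at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and fry were run beside it. The lists of cholesterol synthesis and uptake, fatty acid synthesis, ATF4 stress response, WNT targets, mitochondrial respiratory chain and epithelial markers had 0 tested members and gave no result.

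The fit was tested on simulated data over 31996 probes, with 50 probes changed at each fold size in each of 5 runs. For piroxicam against control, 41.2% of probes changed 1.2-fold, 70.4% at 1.5-fold, 80.8% at 2-fold and 95.2% at 4-fold were called, with a mean of 6 false calls per run. For carprofen the shares were 42%, 78.4%, 80% and 96.8% with 9 false calls, and for robenacoxib 42.4%, 76.8%, 82.8% and 95.2% with 6.8. Far fewer probes changed in these simulations than were called in the data, and the noise was independent between probes with no slide effect. The shares therefore check the fit and do not give its power in these data. In 50 simulations over 612 genes for carprofen, camera called a list of 11 genes shifted by 0.3 on the log2 scale 50 times, and called 2 of 550 unshifted lists. The simulated genes were uncorrelated, so these counts do not cover lists of genes that vary together.

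Alternatives chosen before the data were examined covered the normalization between arrays, the background correction, the authors' values, the filter on dim probes, slide and replicate blocks, the arrays in the fit, the variance model, a minimum fold, the choice of probe per gene, the correlation in camera, and leaving out each array. The normexp alternatives used the median foreground and background signals with an offset of 50, in place of the mean foreground signal that had been planned. Scaling by the spiked-in transcripts, leaving out control 3 and piroxicam 3 together, and slide as a random block were added after seeing the data. Spiked-in transcripts were used if their mean signal over the arrays was above 1000, and any dimmer one was left out. The spike-in scale was the mean over the 6 transcripts used, each averaged over its spots first. It had been a mean over all 192 spots at once, which was corrected: the transcripts differ widely in level, so outlier flags on spots of single arrays moved that mean, and the shifts it gave were 0.23 with piroxicam, 0.333 with carprofen and 0.237 with robenacoxib in place of 0.164, 0.323 and 0.25. The offset in normexp draws the fold changes of dim probes toward 0.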

Results

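Messenger RNA was profiled on 12 one-colour arrays of the dog oral melanoma line Mi/CMM1, 3 each of untreated cells and of cells exposed to piroxicam, carprofen or robenacoxib. Piroxicam is an oxicam, carprofen an arylpropionic acid and robenacoxib a phenylacetic acid derivative, and their concentrations differed. Between 66.2% (piroxicam 3) and 80.0% (carprofen 2) of the spots were well above background. Arrays of a group correlated at 0.9946 to 0.9982 across probes, and arrays of different groups at 0.9901 to 0.9975. Changes below are on the log2 scale relative to each array's 75th percentile, with limma's standard error (SE), and adjusted p-values are Benjamini-Hochberg values from limma. This reference matters: scaling to the transcripts spiked in during labelling moved the log2 changes up by 0.164 with piroxicam, 0.323 with carprofen and 0.25 with robenacoxib, to medians of 0.142, 0.3 and 0.22, and 92%, 99.6% and 98.9% of the changed probes were then higher, against 42.5%, 40.7% and 43.1% as scaled here. A gene said to have fallen therefore fell relative to the array as a whole. The p-values measure the spread between arrays of the same group, pooled over the 4 groups. Where the groups compared share no slide, p-values without a slide term do not cover differences between slides. How separate the cultures of a group were is not given.

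The series asked how 3 anti-inflammatory drugs change gene expression in melanoma cells. MYC, a transcription factor that drives growth, stood at 0.46 ± 0.03 (mean ± SD, n = 3, log2 of signal relative to the array's 75th percentile) in control cells, 1.09 ± 0.02 with piroxicam, 0.02 ± 0.03 with carprofen and 0.54 ± 0.05 with robenacoxib. PTGS2, the inducible cyclooxygenase that these drugs inhibit, stood at -3.23 ± 0.05, -3.72 ± 0.08, -2.76 ± 0.03 and -2.93 ± 0.06 in the same order. TGM1, a transglutaminase of the epidermal barrier, stood at -3.39 ± 0.11, -4.00 ± 0.09, -2.79 ± 0.08 and -3.20 ± 0.05. In total 15351 of 31996 probes (48%) differed among the 4 groups in the overall F-test of limma. Most changes were small: the median absolute log2 change among probes called against control was 0.21 with piroxicam, 0.2 with carprofen and 0.2 with robenacoxib. The standard errors grew with slide as a block, from a median of 0.053 to 0.092, 0.069 and 0.115, and fewer probes were called. Each of these 3 block estimates reaches control through carprofen 1 alone, the only drug array on the controls' slide.

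**Figure D1:**
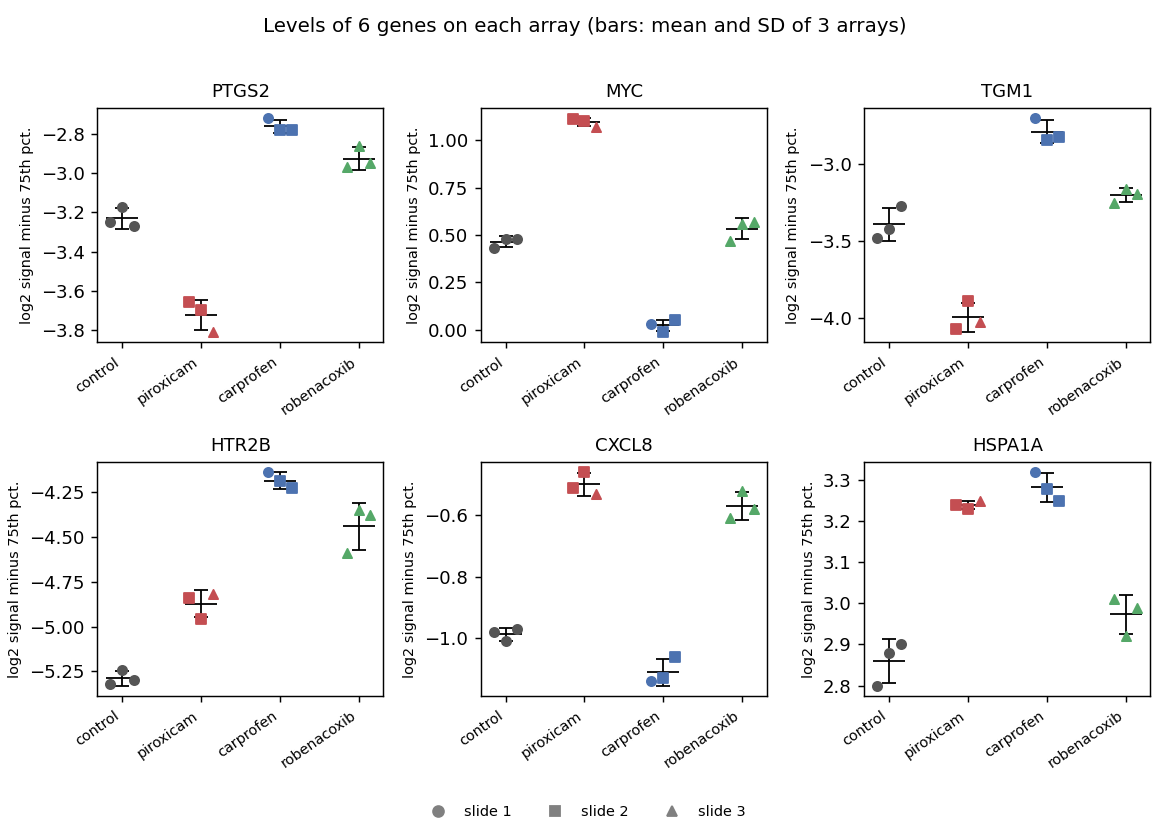
Signal of 6 genes on each array (log2 relative to the array's 75th percentile, vertical axis) by group (horizontal axis); markers show the slide, and bars the mean and SD of 3 arrays. The genes were picked after their values were seen. MYC was highest with piroxicam (1.09 ± 0.02) and lowest with carprofen (0.02 ± 0.03), and PTGS2 the reverse (-3.72 ± 0.08 and -2.76 ± 0.03).

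**Figure D2:**
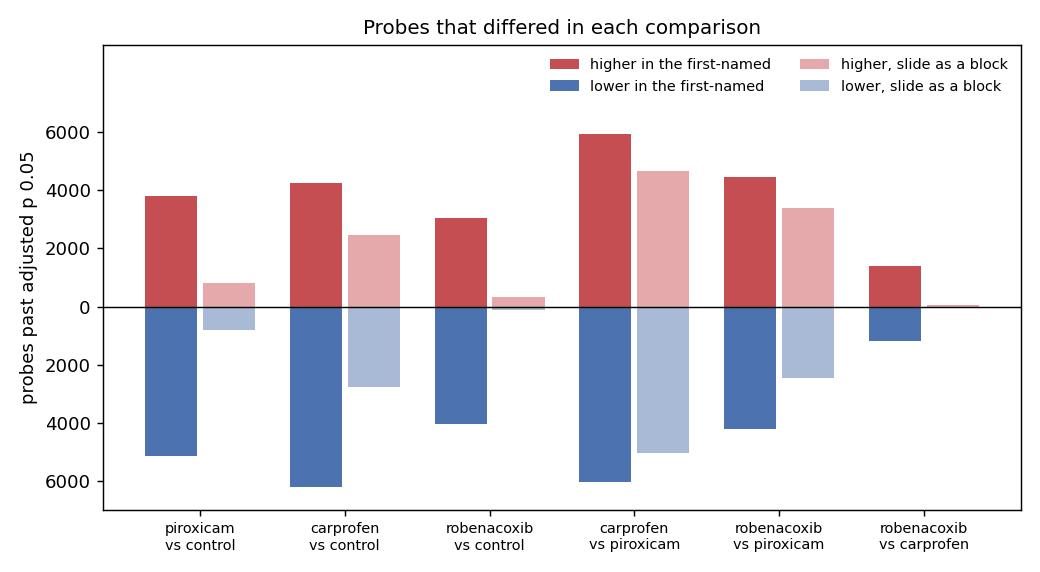
Number of probes called higher and lower (adjusted p below 0.05, limma) in each of the 6 comparisons, with no slide term and with slide as a block. Robenacoxib against control went from 3062 higher and 4044 lower probes to 327 and 124.

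In cells given piroxicam, MYC rose 1.55-fold (log2 change 0.63, SE 0.03, adjusted p = 4.8e-06, n = 3 against 3). VEGFA, a growth factor for blood vessels, rose 1.44-fold (0.53, SE 0.04) and CXCL8, a neutrophil-attracting chemokine, rose 1.4-fold (0.49, SE 0.03) with the same direction called on 4 of 4 probes. PTGS2 fell by 0.49 on the log2 scale (1.41-fold lower, SE 0.05, adjusted p = 0.000108), and BCL2L2, an inhibitor of apoptosis, fell by 0.51 (1.42-fold lower, SE 0.04). BRD2, a reader of acetylated histones, fell by 0.42 (SE 0.02) with 3 of 3 probes called. All of these genes were called in the same direction with slide as a block, where MYC changed by 0.66 (adjusted p = 0.00565) and PTGS2 by -0.40 (adjusted p = 0.0289).

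Of 8 tested genes of prostanoid synthesis and reception, 1 rose and 2 fell with piroxicam (also 1 and 2 adjusted over the list alone). The prostaglandin F receptor gene PTGFR rose by 0.46 (SE 0.04), a call that ended with normexp background correction and 75th-percentile scaling (0.23). PTGER2, a prostaglandin E2 receptor gene, was lower by a measured log2 difference of -0.83 (SE 0.16) but was well above background on 1 of 3 piroxicam arrays, and its call ended with slide as a block (-0.67, adjusted p = 0.196), with quantile normalization, with both normexp settings and in the authors' values. PTGS1, the constitutive cyclooxygenase, differed by 0.98 with an SE of 0.59 (adjusted p = 0.247), by 0.16 without piroxicam 3 and by -0.39 with slide as a block, so its direction is not settled. PTGES, a prostaglandin E synthase, differed by -0.25 (adjusted p = 0.118; -0.16 with slide as a block), which passed when piroxicam 2 was left out (-0.35) and with a replicate block. Among 4 interferon response genes 2 fell (also 2 adjusted over the list alone), of which MX1, an antiviral GTPase, fell by 0.31 (SE 0.02) on 2 of 2 probes. Among 4 heat shock genes 1 rose and 1 fell, both also adjusted over the list alone. HSPA1A, the stress-inducible HSP70, rose by 0.38 (SE 0.04), with 4 of 4 probes called, and HSPA4 fell by 0.19 (SE 0.04), a call that ended with quantile normalization, with spike-in scaling (-0.03) and with slide as a block (-0.13, adjusted p = 0.32). Of 11 apoptosis regulators 2 rose and 2 fell (2 and 3 adjusted over the list alone); beside BCL2L2, CASP9, an initiator caspase, rose by 0.15 (SE 0.04), which did not pass with slide as a block (0.16 with a larger standard error, adjusted p = 0.263) or with normexp and 75th-percentile scaling.

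Among 6 lysosome genes 2 rose and 2 fell (2 and 2 adjusted over the list alone), and NPC1, which exports cholesterol from lysosomes, rose by 0.28 (SE 0.04) on 2 of 2 probes. PPARD, a nuclear receptor and the 1 tested gene of the fatty acid oxidation list, rose by 0.30 (SE 0.04). CXCL8 was the 1 gene called among 6 inflammatory cytokine genes, also adjusted over the list alone. In the hypoxia and glycolysis list of 3, 2 rose, VEGFA among them, and GAPDH fell (2 and 1 adjusted over the list alone); GAPDH changed by -0.33 (SE 0.07) but by 0.05 with normexp and quantile normalization and 0.03 in the authors' values, and by -0.06 with slide as a block. Both metallothionein genes tested fell relative to the array (also 2 adjusted over the list alone) but were no longer lower with spike-in scaling, and neither passed with slide as a block; MT1E changed by -0.16 (SE 0.03) as scaled here and by 0 against the spikes. MYC was the 1 gene called of 2 immediate early genes, and 1 lower gene each was called in the lists of mitosis (2 tested), NRF2 (2) and xenobiotic metabolism (6), the same adjusted over the list alone and none with slide as a block. In the lists of endoplasmic reticulum chaperones (3 tested), ribosomal proteins (3), pigment genes (4), p53 targets (2) and replication genes (1), 0 genes passed. Adjusted over the list alone, 1 p53 target was higher. Markers of other cell types gave 1 higher and 2 lower of 5 fibroblast genes (2 and 2 adjusted over the list alone), none of which passed with slide as a block; the leukocyte genes CD4 (0.28, SE 0.27) and CD8A (0.02, SE 0.40) and the endothelial gene VWF (0.06, SE 0.07) did not pass. CD8A differed by 1.72 with slide as a block (adjusted p = 0.0439). No list was called by camera (0 of 12, lowest adjusted p = 0.641, 0 at an unadjusted p below 0.05, 0 with an estimated correlation), while fry called 4 lists for a one-way shift and 8 for change in either direction. Fry tests whether the genes of a list move on balance in 1 direction, or in either direction, and does not compare them with other genes.

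In all, 3805 probes were higher and 5145 lower with piroxicam than in control, and 69 and 98 of 614 named genes. At 2-fold or more, 26 probes were higher and 135 lower, of which 16 and 18 were well above background on all 12 arrays. Among probes without a name here, A_11_P000002899 fell by 1.41 (SE 0.03, adjusted p = 1.35e-07). No slide held both groups, and with slide as a block 805 probes were higher and 824 lower. Of the original calls 98.8% kept their sign and 16.3% stayed called. The block fit uses the arrays that made the calls, so kept signs are no separate support, here or for the other drugs. Control 3 and piroxicam 3 stood apart on the first principal component, and without both arrays 2268 probes were higher and 2512 lower.

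In cells given carprofen, HTR2B, a serotonin receptor gene, rose 2.14-fold (log2 change 1.10, SE 0.07, adjusted p = 7.05e-06, n = 3 against 3). PTGS2 rose 1.39-fold (0.47, SE 0.05, adjusted p = 0.000111), and TGM1 rose 1.51-fold (0.60, SE 0.07). MYC fell by 0.44 on the log2 scale (1.35-fold lower, SE 0.03, adjusted p = 2.11e-05), and GALNS, a lysosomal sulfatase, fell by 0.45 (SE 0.05). Spike-in scaling moved every change with carprofen up by 0.323, so the falls of MYC and GALNS were much smaller on that scale. BIRC5, which encodes the mitotic apoptosis inhibitor survivin, fell by 0.34 (SE 0.04). CRYGS, a lens crystallin gene, rose by 0.59 (SE 0.06), EPB41L5 by 0.69 (SE 0.10) and HSD17B14, a hydroxysteroid dehydrogenase, by 0.38 (SE 0.03). The calls of all 9 genes held with slide as a block, an estimate that rests on carprofen 1 against the 3 controls of its slide: HTR2B changed by 1.14 (adjusted p = 0.000835), PTGS2 by 0.51 (adjusted p = 0.00196) and MYC by -0.43 (adjusted p = 0.00232), while EPB41L5 shrank to 0.45 (adjusted p = 0.033), and carprofen 1 lay outside the range of the controls for HTR2B, PTGS2 and MYC. Normexp with quantile normalization kept the calls but gave smaller changes for HTR2B (0.55), PTGS2 (0.30), EPB41L5 (0.32), CRYGS (0.39) and BIRC5 (-0.15).

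Both mitosis genes tested, BIRC5 and CCNB3, fell relative to the array (also 2 adjusted over the list alone), CCNB3 by 0.21 (SE 0.04), although with scaling by the spiked-in transcripts CCNB3 stood at 0.11 and BIRC5 at -0.01. CCND1, the G1 cyclin and the 1 tested gene of the replication list, fell by 0.23 (SE 0.03) relative to the array but stood at 0.09 with spike-in scaling, and its call ended with normexp and quantile normalization and in the authors' values. Both metallothionein genes fell relative to the array (also 2 adjusted over the list alone), MT1E by 0.25 (SE 0.03) and MT2 by 0.28 (SE 0.05), and stood at 0.07 and 0.04 with spike-in scaling. Of 11 apoptosis regulators 4 rose and 1 fell (4 and 3 adjusted over the list alone). DIABLO, which frees caspases from their inhibitors, fell by 0.26 (SE 0.03) relative to the array and stood at 0.06 with spike-in scaling. The antiapoptotic MCL1 and BCL2 rose by 0.18 and 0.16 (SE 0.04 each), calls that ended with slide as a block (0.10 and 0.13, adjusted p = 0.201 and 0.143) and with normexp and 75th-percentile scaling.

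Of the 8 prostanoid genes 2 rose with carprofen, PTGS2 and PTGFR (also 2 adjusted over the list alone). PTGFR changed by 0.23 (SE 0.04), and its call ended with quantile normalization, both normexp settings and the authors' values. PTGS1 differed by 0.37 (SE 0.59, adjusted p = 0.684; 0 with slide as a block) and PTGES by -0.09 (SE 0.11, adjusted p = 0.605). HSPA1A rose by 0.42 (SE 0.04) with 4 of 4 probes called, and the 4 heat shock genes gave 1 higher and 1 lower (also 1 and 1 adjusted over the list alone). VEGFA rose by 0.25 (SE 0.04) on its brighter probe, while its other probe changed by -0.21, so the probes disagree; its list of 3 gave 1 higher and 1 lower, also adjusted over the list alone. Of 3 ribosomal protein genes RPL27 fell, by 0.27 (SE 0.03) relative to the array and not under spike-in scaling (0.05), also 1 adjusted over the list alone. CTSD, a lysosomal protease, was the 1 gene called of 6 in the lysosome list (also 1 adjusted over the list alone), which does not hold GALNS. CTSD fell by 0.25 (SE 0.03) relative to the array and stood at 0.07 with spike-in scaling. VHL, the ubiquitin ligase component that marks hypoxia-inducible factors for degradation, fell by 0.39 (SE 0.06) on 1 of 2 probes.

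MITF, the melanocyte master regulator, fell by 0.13 (SE 0.03) relative to the array, the 1 gene called of 4 pigment genes (also 1 adjusted over the list alone); its call ended with slide as a block (-0.10, adjusted p = 0.102) and with normexp and 75th-percentile scaling, and it stood at 0.20 with spike-in scaling. CYP3A12, a canine drug-metabolising cytochrome, rose by 0.62 (SE 0.11), the 1 gene called of 6 in the xenobiotic list (also 1 adjusted over the list alone), with a change of 0.42 and an adjusted p = 0.051 with slide as a block. The inflammatory list of 6 gave 2 lower genes and the interferon list of 4 gave 1 higher, the same counts as adjusted over the list alone, and none of them passed with slide as a block. Both NRF2 genes tested were lower relative to the array (also 2 adjusted over the list alone), higher with spike-in scaling, and not called with slide as a block; FTL changed by -0.19 (SE 0.04), by 0.13 against the spikes, and lost its call with quantile normalization, both normexp settings and the authors' values. The lists of p53 targets (2 tested), chaperones of the endoplasmic reticulum (3) and fatty acid oxidation (1, PPARD) gave 1 lower gene each, also adjusted over the list alone, none called with slide as a block and all positive with spike-in scaling. MYC was the 1 gene called of 2 immediate early genes. Among 5 fibroblast markers 2 were lower (1 higher and 2 lower adjusted over the list alone), while CD4 (0.27, SE 0.27), CD8A (-0.10, SE 0.40) and VWF (0.07, SE 0.07) did not pass; with slide as a block CD8A differed by 1 (adjusted p = 0.049). Camera called 0 of 12 lists (lowest adjusted p = 0.605, 0 at an unadjusted p below 0.05, 0 with an estimated correlation), and fry called 7 for a one-way shift and 6 for change in either direction.

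In all, 4266 probes were higher and 6228 lower with carprofen, and 69 and 146 of the 614 named genes. At 2-fold or more, 65 probes were higher and 10 lower. Among probes without a name here, A_11_P0000041829 rose by 1.84 (SE 0.06, adjusted p = 1.26e-06) and A_11_P0000040421 fell by 1.15 (SE 0.04, adjusted p = 1.03e-06). With slide as a block 2466 probes were higher and 2766 lower, 100% of the original calls kept their sign and 44.1% stayed called. A fit to slide 1 alone, 1 carprofen array against 3 controls, called 0 probes higher and 1 lower, so the block calls depend on the spread estimated from the other slides.

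In cells given robenacoxib, HTR2B rose 1.8-fold (log2 change 0.85, SE 0.07, adjusted p = 4.19e-05, n = 3 against 3) and CXCL8 rose 1.34-fold (0.42, SE 0.03, adjusted p = 6.29e-05) on 4 of 4 probes. PTGS2 rose 1.23-fold (0.30, SE 0.05, adjusted p = 0.00193). VPS52, part of a complex that returns vesicles to the Golgi, fell by 0.53 on the log2 scale (1.44-fold lower, SE 0.04, adjusted p = 2.57e-05) on 1 of 4 probes, the others not being called. CTXN1 fell by 0.42 (SE 0.06), GALNS by 0.40 (SE 0.05) and AMN, part of the intestinal vitamin B12 receptor, by 0.39 (SE 0.04). Only VPS52 among these genes was still called with slide as a block (-0.55, adjusted p = 0.0354). HTR2B then changed by 0.83 (adjusted p = 0.0633), CXCL8 by 0.42 (adjusted p = 0.0596) and PTGS2 by 0.49 (adjusted p = 0.0561), while AMN moved to -0.22. With normexp and quantile normalization HTR2B changed by 0.50, AMN by -0.24 and VPS52 by -0.28.

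Of the 8 prostanoid genes 3 rose with robenacoxib (3 higher and 1 lower adjusted over the list alone). Beside PTGS2, PTGFR changed by 0.22 (SE 0.04), a call that ended with quantile normalization, both normexp settings, the authors' values and slide as a block. PTGS1 differed by 0.84 (SE 0.59, adjusted p = 0.356) and by -2.17 with slide as a block (adjusted p = 0.117), so its direction is not settled, although it was called without piroxicam 3 (0.84). PTGES differed by -0.34 (SE 0.11, adjusted p = 0.0569), by -0.06 with slide as a block and by -0.02 with normexp and 75th-percentile scaling, and was called without piroxicam 2 (-0.34), piroxicam 3 (-0.34) or robenacoxib 2 (-0.42), with scaling by the median, with only probes above background on all arrays and with a replicate block. Among 11 apoptosis regulators 2 rose and 2 fell (2 and 4 adjusted over the list alone). MCL1 rose by 0.26 (SE 0.04) and BCL2 by 0.19 (SE 0.04), and DIABLO fell by 0.22 (SE 0.03) relative to the array but stood at 0.03 with spike-in scaling and lost its call with normexp and quantile normalization and in the authors' values. CCND1 fell by 0.22 (SE 0.03) relative to the array and stood at 0.03 with spike-in scaling. Both mitosis genes and both metallothionein genes were lower (2 and 2, the same adjusted over the list alone), BIRC5 by a log2 change of -0.18 (SE 0.04) and MT1E of -0.17 (SE 0.03), and all 4 turned positive with spike-in scaling, at 0.07 for BIRC5 and 0.08 for MT1E. Both calls ended with either normexp setting and in the authors' values, and that of BIRC5 also in a fit to the 2 groups alone. No gene of this paragraph passed with slide as a block, where MCL1 changed by 0.14, BCL2 by 0.14, DIABLO by -0.21, CCND1 by -0.27, BIRC5 by -0.13 and MT1E by -0.15. MYC changed by 0.07 (SE 0.03, adjusted p = 0.133) and HSPA1A by 0.11 (SE 0.04, adjusted p = 0.0593), and neither passed as scaled here. Spike-in scaling moved both up by 0.25, like every probe with robenacoxib. MITF, at 0.09 (SE 0.03, adjusted p = 0.054), did not pass either, but was called without piroxicam 3 (0.09) or carprofen 2 (0.09), with trend and robust variance and with spike-in scaling (0.34).

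CXCL8 was the 1 gene called of 6 inflammatory cytokine genes (also 1 adjusted over the list alone). Of 6 xenobiotic genes 1 was higher (2 higher and 1 lower adjusted over the list alone). Of 3 genes in the endoplasmic reticulum chaperone list 1 was higher, SEC61B, which encodes a translocation channel subunit and not a chaperone. Of 3 ribosomal protein genes 1 was lower. The counts of these last lists were unchanged over the list alone. The interferon list of 4 gave 1 lower gene and the p53 list of 2 gave 1 higher (1 and 1 lower adjusted over the list alone). The hypoxia list of 3 gave 1 higher and 1 lower. In their lists, 0 of 4 heat shock genes, 0 of 4 pigment genes and 0 of 6 lysosome genes passed. So did 0 of 2 NRF2 genes and 0 of 2 immediate early genes. Adjusted over the list alone, 1 pigment gene was higher. The lysosomal enzyme genes GALC and GALNS, both called with robenacoxib, are not on the lysosome list. Among 5 fibroblast markers 2 were lower (also 2 adjusted over the list alone), while CD4 (-0.04, SE 0.27), CD8A (-0.07, SE 0.40) and VWF (0.03, SE 0.07) did not pass. No member of these lists passed with slide as a block. Camera called 0 of 12 lists (lowest adjusted p = 0.609, 0 at an unadjusted p below 0.05, 0 with an estimated correlation), and fry called 4 for a one-way shift and 4 for change in either direction.

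In all, 3062 probes were higher and 4044 lower with robenacoxib, and 43 and 102 of the 614 named genes. At 2-fold or more, 32 probes were higher and 12 lower, of which 16 and 4 were well above background on all 12 arrays. Among probes without a name here, A_11_P0000014469 rose by 2.67 (SE 0.04, adjusted p = 2.09e-09), and by 2.61 with slide as a block (adjusted p = 0.000136). No slide held both groups, and with slide as a block 327 probes were higher and 124 lower; 96.6% of the original calls kept their sign and 5.1% stayed called. Without control 1, 2 or 3 or robenacoxib 2 the lower probes numbered 2673, 2488, 2562 and 2689.

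Across the 3 drugs, HTR2B rose with each, by 0.42 (SE 0.07) with piroxicam, 1.10 with carprofen and 0.85 with robenacoxib. GALC, a lysosomal galactosidase, rose by 0.34, 0.22 and 0.32 (SE 0.02 each) and HSD17B14 by 0.20, 0.38 and 0.34 (SE 0.03 each). AMN fell by 0.27, 0.36 and 0.39 (SE 0.04 each). LIFR, the receptor for leukaemia inhibitory factor, was lower by log2 changes of -0.27, -0.25 and -0.28 (SE 0.06 each), which shrank to -0.03, -0.09 and -0.02 with slide as a block, and its carprofen value was 0.08 with spike-in scaling. With slide as a block the calls of GALC held for piroxicam (0.33) and carprofen (0.22) but not robenacoxib (0.31, adjusted p = 0.0587), and those of HTR2B, HSD17B14 and AMN held for carprofen alone. In the calls lost, HTR2B kept its size (0.45 with piroxicam, 0.83 with robenacoxib) and HSD17B14 nearly so (0.17 and 0.33), while AMN shrank to -0.11 and -0.22. No call of LIFR held; the carprofen call of LIFR also ended in a fit to the 2 groups alone. Normexp with 75th-percentile scaling ended the piroxicam calls of HTR2B and GALC, and normexp with quantile normalization those of AMN with piroxicam and GALC with carprofen. In total 827 probes were higher and 1253 lower with all 3 drugs, as were 12 and 34 named genes. Simulated unchanged groups, compared with simulated controls that they shared, gave 0 and 0. That simulation held no changed probe, so few calls were to be expected. It does not measure the overlap among drugs that each change many probes against shared controls. Independent lists of these sizes gave 48.6 and 126.6. The 3 controls could not be divided to keep 2 in each part, so part of the excess may come from the shared controls. A slide block left 85 probes that were higher and 46 lower with all 3; without control 2 the higher count was 521, and without control 1, 2 or 3 the lower count was 792, 696 and 700.

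Fold changes against control correlated across probes at 0.33 for piroxicam and carprofen, 0.49 for piroxicam and robenacoxib and 0.70 for carprofen and robenacoxib, where shared controls alone gave 0.5 in simulation; probes are not independent replicates. The covariances were 0.0235, 0.032 and 0.0406, and exceeded the simulated ones by 0.0099, 0.0185 and 0.0269. The correlations with slide as a block were 0.65, 0.58 and 0.66, against 0.75, 0.80 and 0.60 in simulation, and the covariance exceeded the simulated one by 0.0358, 0.0151 and 0.0458. Probes called in opposite directions numbered 1475 for piroxicam and carprofen, among them those of MYC, PTGS2 and TGM1, 565 for piroxicam and robenacoxib, and 73 for carprofen and robenacoxib. TGM1 fell by 0.61 (SE 0.07) with piroxicam, a call that ended with slide as a block (-0.47, adjusted p = 0.0761).

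Comparing carprofen with piroxicam directly, TGM1 was 2.31-fold higher with carprofen (log2 difference 1.21, SE 0.07, adjusted p = 1.65e-06, n = 3 against 3) and PTGS2 was 1.95-fold higher (0.96, SE 0.05, adjusted p = 7.99e-07). MYC was 2.1-fold lower with carprofen (-1.07, SE 0.03, adjusted p = 1.06e-07), and CXCL8 was 1.53-fold lower (-0.61, SE 0.03) on 4 of 4 probes. NICN1 was lower by a log2 difference of -0.71 (SE 0.03), KLK1, tissue kallikrein, of -0.62 (SE 0.12) on 1 of 2 probes, and PODXL, the sialomucin podocalyxin, of -0.55 (SE 0.09). HGFAC, the activator of hepatocyte growth factor, was 2.5-fold higher (1.32, SE 0.10), but was well above background on 2 of 3 piroxicam arrays, and differed by 0.45 with normexp and quantile normalization and 0.66 in the authors' values. Slide 2 held 2 arrays of each drug, and within it these differences were 1.15 for TGM1, 0.90 for PTGS2, -1.09 for MYC, -0.61 for CXCL8, -0.69 for NICN1, -0.52 for KLK1, -0.49 for PODXL and 1.29 for HGFAC, each without overlap of the arrays. These are also the slide-block estimates, since both drugs meet on this slide alone. SAG, a retinal arrestin gene above background on 0 piroxicam arrays, was at least 1.22-fold higher with carprofen (adjusted p = 0.00118, and 0.0123 with slide as a block), a call that ended with normexp and 75th-percentile scaling. MC1R, the melanocortin receptor of pigment cells, was at least 2.47-fold higher with carprofen (adjusted p = 0.0125), being above background on 0 piroxicam arrays, and was not called with slide as a block (adjusted p = 0.0809) or with normexp and 75th-percentile scaling. NR4A1, an immediate early nuclear receptor, was 1.96-fold higher (0.97, SE 0.21), and not called with normexp and 75th-percentile scaling (0.51). HSPA1A differed by 0.04 with a 95% interval from -0.04 to 0.12 (adjusted p = 0.409).

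Of the 8 prostanoid genes 2 were higher and 1 lower with carprofen than with piroxicam (also 2 and 1 adjusted over the list alone), and of 11 apoptosis regulators 4 were higher and 1 lower (also 4 and 1), the same counts as with slide as a block. In the lysosome list of 6, 1 was higher and 3 lower under each of these settings. The interferon list gave 1 higher of 4, MX1, which differed by 0.41 (SE 0.02) on 2 of 2 probes. Camera called 0 of 12 lists (lowest adjusted p = 0.418, 1 at an unadjusted p below 0.05, 0 with an estimated correlation), and fry called 8 for a one-way shift and 8 for change in either direction. In all, 5956 probes were higher and 6039 lower with carprofen, and 4673 and 5054 with slide as a block. A fit to slide 2 alone called 2591 higher and 1965 lower, and 100% of the original calls had the same sign there. These arrays, like those of slide 3 below, are among the arrays that made the calls, so the shared sign is no separate support. Scaled to the spiked-in transcripts, 89.2% of changed probes were higher, against 49.7% here.

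Robenacoxib and piroxicam also differed in PTGS2, which was 1.74-fold higher with robenacoxib (0.80, SE 0.05, adjusted p = 6.34e-06, n = 3 against 3), and in TGM1, 1.74-fold higher (0.80, SE 0.07, adjusted p = 3.68e-05). CRYGS was 1.46-fold higher (0.55, SE 0.06). KLK1 was lower by a log2 difference of -0.68 (SE 0.12) on 1 of 2 probes, CLDN3, a tight junction gene, of -0.61 (SE 0.14), PODXL of -0.60 (SE 0.09) and NICN1 of -0.57 (SE 0.03). On slide 3, which held 3 robenacoxib arrays and 1 of piroxicam, the differences were 0.88 for PTGS2, 0.83 for TGM1, 0.62 for CRYGS, -0.67 for KLK1, -0.76 for CLDN3, -0.55 for PODXL and -0.58 for NICN1, each outside the range of the robenacoxib arrays. The slide-block estimate is this same difference, so it too rests on piroxicam 3 alone; with the spread taken from all slides the 7 genes were called. CLDN3 differed by -0.37 and PODXL by -0.39 with normexp and 75th-percentile scaling. CXCL8 differed by -0.07 (adjusted p = 0.166). Of the 8 prostanoid genes 2 were higher and 1 lower (3 and 1 adjusted over the list alone), and of 11 apoptosis regulators 4 were higher (4 and 1 lower adjusted over the list alone). Camera called 0 of 12 lists (lowest adjusted p = 0.205, 1 at an unadjusted p below 0.05, 0 with an estimated correlation), and fry called 6 and 7. In all, 4446 probes were higher and 4219 lower with robenacoxib, and 3379 and 2474 with slide as a block; a fit to slide 3 alone called 0 and 0, and 100% of the original calls had the same sign there. Higher probes made up 82.8% of those changed with spike-in scaling, against 51.3% here.

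Robenacoxib and carprofen differed least in number of probes. CXCL8 was 1.45-fold higher with robenacoxib (0.54, SE 0.03, adjusted p = 9.06e-05, n = 3 against 3) on 4 of 4 probes, and MYC was 1.43-fold higher (0.51, SE 0.03, adjusted p = 8.07e-05). Both calls held with slide as a block (adjusted p = 0.0271 and 0.0288). ESRRA, an orphan nuclear receptor, was 1.21-fold higher (0.27, SE 0.02) on 1 of 2 probes, CTSS, a lysosomal protease, was 1.34-fold lower (-0.43, SE 0.07), and TGM1 was 1.33-fold lower (-0.41, SE 0.07). The calls of ESRRA, CTSS and TGM1 ended with slide as a block, where the differences were 0.28, -0.35 and -0.32 with larger standard errors (adjusted p = 0.0659, 0.343 and 0.314); that of CTSS also with both normexp settings and the authors' values, and that of TGM1 with normexp and 75th-percentile scaling and in a fit to the 2 groups alone. PTGS2 differed by -0.17 with a 95% interval from -0.27 to -0.06 (adjusted p = 0.0594), CRYGS by -0.16 (-0.29 to -0.03, adjusted p = 0.133), GALNS by 0.05 (-0.05 to 0.16, adjusted p = 0.542) and PTGFR by -0.01 (-0.11 to 0.08, adjusted p = 0.897), and none of these passed.

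The 3 tested genes of the endoplasmic reticulum chaperone list were higher as a set with robenacoxib than with carprofen (camera, adjusted p = 0.0446). Camera gave adjusted p = 0.224 with an estimated correlation and 0.252 with slide as a block, and spike-in scaling ended the call too. SEC61B, a subunit of the protein translocation channel and not itself a chaperone, was the 1 member called, higher by 0.14 (SE 0.02). The chaperones HSP90B1 and CANX were not called. They differed by 0.11 (SE 0.03, adjusted p = 0.0558) and 0.11 (SE 0.05, adjusted p = 0.209), and 3 of 3 passed when adjusted over the list alone. It was the 1 list of 12 called (1 at an unadjusted p below 0.05, 0 with an estimated correlation), the call ended without control 1 or 3, piroxicam 1, 2 or 3, carprofen 2 or robenacoxib 2 or 3, and fry called 5 for a one-way shift and 8 for change in either direction. In all, 1413 probes were higher and 1196 lower with robenacoxib, and 29 and 24 of the named genes. No slide held both drugs, and with slide as a block 41 probes were higher and 40 lower. Of the changed probes 54.2% were higher, against 66.2% with scaling by the median, 43.1% with normexp and quantile normalization, 44.1% in the authors' values and 8.4% with spike-in scaling. Leaving out carprofen 2 or 3 or robenacoxib 1, 2 or 3 gave 740, 702, 719, 574 and 864 higher probes and 704, 679, 700, 582 and 764 lower ones.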

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

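All tests of the first and second pattern below, and the covariance and slide checks of the third, were chosen only after the result was seen; the checks of the third with quantile normalization and without single arrays had been set earlier.

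Relative to the 6 spiked-in transcripts with a mean signal above 1000, the array level was higher with each drug. The log2 difference was 0.16 with piroxicam, 0.32 with carprofen and 0.25 with robenacoxib, with these 6 spikes of the same sign. Any dimmer spike was not used. The exact permutation p for 3 arrays against 3 was 0.1, the smallest possible. Carprofen 1 lay 0.29 above the highest control on the same slide, which speaks against slide for carprofen but rests on that array alone. No piroxicam or robenacoxib array shares that slide, and for these drugs slide stays open. Pipetting errors of single tubes are a poor explanation for all 3, since the smallest drug difference was 4.6 times the largest SD within a group. An RNA or spike amount that differed by group would give what was seen, with 0 drug arrays at or below the highest control, and so would more messenger RNA per total RNA; these could be told apart by remeasuring RNA input and adding spikes per cell.

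PTGS2 was higher and MYC lower with carprofen than with piroxicam. A slide effect is a poor explanation, as within slide 2 the smaller of both differences was 0.9, and so is background subtraction, as with normexp it was at least 0.67. Exchanged drug names or doses could not be tested from the values, and the labels do conflict on which drug was given at 779 µM; a quantitative PCR of PTGS2 and MYC in cells treated anew with each drug at both concentrations would decide this.

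The changes with carprofen and robenacoxib were more alike than either was to those with piroxicam. These drugs share no slide, and their covariance in excess of the simulated one led the other pairs by 0.0084 (0.003 to 0.014 without single arrays, 0.01 with slide as a block), which speaks against slides shared by drugs. A brightness trend between arrays is a poor explanation, the correlation being 0.24 above that of piroxicam and robenacoxib after quantile normalization, and a single array likewise, the order holding in 12 of 12 fits without 1 array. The correlations with slide as a block were 0.65 for piroxicam and carprofen, 0.58 for piroxicam and robenacoxib and 0.66 for carprofen and robenacoxib, against 0.75, 0.80 and 0.60 simulated for unchanged groups, so only carprofen and robenacoxib exceeded the simulated value.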

How the results depend on the processing

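Scaling by the spiked-in transcripts, leaving out control 3 and piroxicam 3 together and slide as a random block were chosen only after the result was seen. Every other alternative was chosen before the data were examined, but the normexp settings were run on median signals in place of the planned mean foreground signal.

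The main limit is the layout: control shares no slide with piroxicam or robenacoxib, and slide and scan are the same, so a separate scan block could not be fitted. The slide block reaches control through carprofen 1 alone. Of 172 calls on named genes, 50 stayed called the same way under every alternative set beforehand that was fitted to them (at most 23 per gene, the minimum fold and the averaging of probes not among them), and 75 when the slide block is left aside. Scaling to the array level hides any change in total messenger RNA. Except where the construction of the alternative shows it, the cause was not tested. Replicate numbers do not mark pairs: 18 pairs with the same number correlated at -0.45 to 0.2, 3 of them over 0.1. With a replicate block as for pairing, robenacoxib against carprofen gave 710 higher and 665 lower probes.

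With slide as a block, piroxicam gave 805 higher and 824 lower probes, carprofen 2466 and 2766, robenacoxib 327 and 124, all 3 drugs 85 and 46; robenacoxib against piroxicam 2474 lower, and against carprofen 41 and 40. FTL with piroxicam stood at 0.02 and ADM with robenacoxib at 0. Slide as a random block (consensus correlation 0.155; lists not run) left robenacoxib with 2316 lower, all 3 drugs 699 lower, and robenacoxib against carprofen 728 and 647.

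The list of endoplasmic reticulum chaperones called between robenacoxib and carprofen was lost, leaving 0 lists, with quantile normalization, median scaling, both normexp settings, the authors' values, only probes above background on all 12 arrays, slide as a block, the 2 groups alone, an estimated correlation, control 3 and piroxicam 3 left out together, and spike-in scaling.

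Quantile normalization put TXNRD1 with carprofen at 0.01. Normexp with quantile normalization gave 3502 lower probes with carprofen, and 285 higher and 377 lower for robenacoxib against carprofen; FTL with piroxicam stood at 0.02, GAPDH at 0.05 with piroxicam, 0.03 with carprofen and 0.03 with robenacoxib, SULT1A1 with piroxicam at 0.02 and HSP90B1 with carprofen at 0.03. The authors' values gave 3263 lower with carprofen, 2585 lower with robenacoxib, and 245 and 310 for robenacoxib against carprofen; FTL with piroxicam stood at 0.01, GAPDH at 0.03, 0.04 and 0.04 with piroxicam, carprofen and robenacoxib, SULT1A1 with piroxicam at 0.02, HSP90B1 with carprofen at 0.03 and COL1A1 with robenacoxib at 0.01.

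Normexp with the 75th percentile gave 9585 probes that differed among the groups, 2181 higher with piroxicam, 2198 higher and 3249 lower with carprofen, 2363 lower with robenacoxib and 363 higher with all 3. Carprofen against piroxicam gave 3277 and 3455, robenacoxib against piroxicam 2590 and 2067, and robenacoxib against carprofen 97 and 113. SAG, at least 1.75-fold lower with robenacoxib than with carprofen without these settings (above background on 0 robenacoxib arrays; the call also ended without control 2 or any 1 carprofen or robenacoxib array), differed by 0.1, and SULT1A1 with piroxicam stood at 0.01.

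With no filter on dim probes robenacoxib against carprofen gave 695 and 703, and all 3 drugs 820 lower. In fits to the 2 groups alone these were 70 and 140, and 758. A minimum absolute log2 change of 1 left 214 probes among the groups, 26 and 135 with piroxicam, 65 and 10 with carprofen, 32 and 12 with robenacoxib, 283 and 36 for carprofen against piroxicam, 82 and 22 for robenacoxib against piroxicam, 3 and 10 for robenacoxib against carprofen, and 4 and 1 with all 3. Of these 2-fold probes, 94 and 28 for carprofen against piroxicam were well above background on all 12 arrays. For robenacoxib the counts were 20 and 14 against piroxicam, and 1 and 1 against carprofen. Without control 3 and piroxicam 3, piroxicam gave 2268 and 2512, robenacoxib 2335 lower, robenacoxib against carprofen 865 higher, and all 3 drugs 499 and 539.

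Spike-in scaling, which moves every probe of an array by the same amount, gave 23283 probes that differed among the groups, 12850 higher and 1120 lower with piroxicam, 23287 and 99 with carprofen, 19353 and 211 with robenacoxib, 10915 and 32 with all 3, 13231 and 1610 for carprofen against piroxicam, 8085 and 1684 for robenacoxib against piroxicam, and 257 and 2795 for robenacoxib against carprofen. These genes turned positive with piroxicam: FTL 0.03, MT1E 0, MT2 0.02, CTSK 0.04 and COL1A2 0.07. With carprofen these did: PPARD 0.15, HSP90B1 0.19, HSPA4 0.19, FTL 0.13, TXNRD1 0.22, MT2 0.04, MT1E 0.07, BAX 0.15, DIABLO 0.06, CCND1 0.09, CCNB3 0.11, GAPDH 0.09, MITF 0.2, CXCL8 0.2, CTSD 0.07, RPL27 0.05, COL1A1 0.14, COL1A2 0.16, LIFR 0.08 and CYB5R3 0.03. With robenacoxib MT2 stood at 0.07, MT1E 0.08, DIABLO 0.03, CCND1 0.03, BIRC5 0.07, CCNB3 0.1, MX1 0.14, RPL27 0.14, COL1A1 0.13, CYB5R3 0.02 and VHL 0.02.

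Leaving out single arrays, the probes that differed among the groups ran from 12992 to 15535. Against control, higher and lower probes ran from 2748 to 4143 and 3544 to 5316 with piroxicam, 3273 to 4481 and 4733 to 6150 with carprofen, 2138 to 3264 and 2488 to 4352 with robenacoxib, and 521 to 926 and 696 to 1390 with all 3. Carprofen against piroxicam ran from 4930 to 5984 and 5122 to 5995, robenacoxib against piroxicam from 3444 to 4584 and 3285 to 4473, and robenacoxib against carprofen from 574 to 1251 and 582 to 1135. Lists called ran from 0 to 0 in each drug against control and in carprofen against piroxicam, and from 0 to 1 in robenacoxib against piroxicam (1 without piroxicam 1) and in robenacoxib against carprofen.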

Other observations

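The splits of 6 arrays into 3 and 3 below were chosen only after the result was seen; the 100 splits of all 12 arrays were set earlier.

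Between the drugs, the calls of a few genes below 2-fold held under each alternative set beforehand that was fitted to their probe, and ask for a follow-up. The fits within a single slide are not among these alternatives. PODXL and KLK1 were lower with both carprofen and robenacoxib than with piroxicam, and NICN1 as well, by log2 differences of -0.71 (SE 0.03) and -0.57 (SE 0.03). KLK1 was not called on every tested probe of the gene. CLCN1, the muscle chloride channel gene, was 1.89-fold higher with carprofen than with piroxicam (0.92, SE 0.20, adjusted p = 0.00535 by limma with Benjamini-Hochberg adjustment).

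For each comparison of 3 arrays with 3, only 10 splits exist, too few for a share under 0.05. The number of splits with at least as many changed probes as the real one was 1 in each of the 6 comparisons: 8950 for piroxicam against control, 10494 for carprofen and 7106 for robenacoxib, each with 0 as the highest other, 11995 for carprofen against piroxicam with 0, 8665 for robenacoxib against piroxicam with 1, and 2609 for robenacoxib against carprofen with 1. For gene lists it was 10 of 10 in the comparisons with 0 lists called, where the highest other was 0 for piroxicam, 0 for carprofen, 1 for robenacoxib, 2 for carprofen against piroxicam and 2 for robenacoxib against piroxicam, and 1 of 10 for the 1 list called between robenacoxib and carprofen, with 0 as the highest other. Over 100 splits of the 12 arrays, the real one alone reached 15351 probes that differed among the groups (1 of 100, highest other 195). The same held for the 827 probes higher with all 3 drugs (1 of 100, highest other 0) and the 1253 lower (1 of 100, highest other 3). An arbitrary grouping of the arrays is thus a poor explanation of these counts as a whole. The other splits mix groups that differ, so few calls were to be expected in them. They do not show which single calls are false, nor whether shared calls come from the shared controls. Both kinds of split move arrays freely between slides, whereas the real groups lie largely along slides, so neither excludes a slide effect.

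For the lower MYC and higher PTGS2 with carprofen than with piroxicam, slide (0.9 within slide 2) and background subtraction (0.67 with normexp) are poor explanations. A biological cause was not tested. These values compare the drugs with each other and do not test their directions against control, with which piroxicam shares no slide. A dose series of both drugs with PTGS2, MYC and TGM1 measured at 6 h and 24 h would show whether dose or time matters. The higher array level against the spikes, with 0 drug arrays at or below the highest control, could come from more messenger RNA per total RNA. Spikes added during labelling do not show RNA per cell, which spikes added per counted cell before extraction would test. The call of HTR2B with robenacoxib, 0.85 without a slide term and 0.83 with slide as a block, might hold with control and robenacoxib arrays on shared slides.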
